A study of Drosophila melanogaster with 12 samples.

How the data were processed

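RNA was measured in fat bodies, the larval organ of fat storage and secretion, taken from female wandering third-instar Drosophila melanogaster. The 12 libraries form 4 groups of 3. Larvae ate a control diet with 0.15 M sucrose or a high-sugar diet with 0.7 M sucrose, and carried the fat body driver r4-GAL4 with UAS-Dcr2 over either a control stock or a stock with a UAS-driven RNAi hairpin against seven-up (svp), a nuclear receptor of the COUP-TF family. Per the labels' protocols, fat bodies were dissected, sheared and collected by centrifugation, RNA was extracted with Trizol and treated with DNase, ribosomal RNA was removed with RiboZero, and barcoded libraries were read on an Illumina HiSeq. The labels do not say whether the libraries of a group came from separate pools of animals, so p-values measure only the spread between these samples, which may be technical.

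Per the submitters' processing notes, the authors used TopHat 1.3.2, Bowtie 0.12.7, Cufflinks 1.1.0 and edgeR with genome build dm3. The counter, the annotation, the strand setting and the filters are not given in the sources used here. The deposited values are a signal per gene, called normalized abundance in the file, which are in read-like units, not whole numbers and not divided by gene length. Their form is that of read numbers adjusted to a common library size, and the values point to a separate adjustment of the 6 libraries of each diet: the 6 library factors inferred from them multiply to 0.9985 on the control diet and to 0.9997 on high sugar. Inverting that adjustment turned at least 99.85% of the low values of every library into numbers within 0.1 of a whole read, against 13.4% to 43.4% of the deposited values. The factors were found from genes with a group mean under 12, which are part of these low values. In genes with means from 12 to 20, which were not used to find them, the lowest share of a library was 99.73%. The recovered reads over the genes kept numbered 4380768 to 6556065 per library, and the deposited totals ran from 4663394 to 6490130. Because counting error is small at this depth for abundant genes and large for genes with few reads, changes of low genes are the less certain. No value and no recovered read number was at 0, so every gene kept had reads in every library. A gene without reads in even 1 library is therefore not among them and could not be tested. This includes genes read in only some of the groups.

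The table held 9527 rows. The values of the 2 diets had been joined by gene symbol without regard to case, which left 156 rows with 80 names that differ only in case or repeat a name. These rows were left out of all tests, as were 4 names that are bare numbers. The 9367 genes kept all had a mean of at least 1, so the filter set before the data were examined removed none of them. Gene symbols are printed as deposited. The reference at hand is build BDGP6 and not dm3, so it served only for identifiers, synonyms and chromosome arms, and no coordinate is given: 7013 symbols matched a current symbol, 2237 matched 1 synonym, 81 were ambiguous and 36 had no match. Overlapping genes, antisense genes and near-identical copies could share reads, since the counting is not stated to use strand.

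All tests used limma 3.58.1 in R 4.3.3 on log2(value + 1), with an intensity trend, 1 model over the 12 libraries and 4 group means, and Benjamini-Hochberg adjustment over the 9367 genes. A call is an adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. There were 5 contrasts: high sugar against control diet in each genotype, the libraries labelled svp RNAi against control on each diet, and the interaction, which is the diet contrast in the libraries labelled svp RNAi minus that in control. The genotype contrasts and the interaction used the deposited values, where each difference lies within a diet. The diet contrasts cross the separately adjusted values, whose median over genes differed by 0.107 on the log2 scale between diets, so they were fitted on the recovered reads scaled jointly by the median of ratios, after which the median differed by -0.009. This departs from the plan made before the data were examined, which used the deposited values, and the planned fit is given as an alternative. edgeR was not run on the recovered reads, and limma voom took its place as an alternative chosen after seeing the data.

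Before the data were examined, 46 gene lists were fixed: 32 of pathways or complexes, 12 of markers of other cell types and 2 that check labels. They were tested with camera at a preset correlation between genes of 0.01, adjusted over the 46 lists, and again with an estimated correlation and with fry. With an estimated correlation no list passed in any contrast. The genes named were chosen by a rule fixed at the same time. It takes svp, InR and the transgene and landing-site genes, the 5 higher and 5 lower genes with the largest fold change among calls whose 3 against 3 libraries do not overlap, and up to 4 called members of each list that passed or had at least 2 calls, by smallest p and in the order of the lists' p until about 30 genes were taken. Where fewer than 2 members were called, the 2 with the smallest p were named as values. For the diet contrast in the libraries labelled svp RNAi and for the interaction it takes the 5 called genes with the largest change in each direction. Genes named outside the rule are marked so.

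The scripts were tested on simulated reads for the real genes with 200 changed genes per contrast. For 2-fold changes, 50.7% were called in the diet contrast in control, 59.7% in the diet contrast in the libraries labelled svp RNAi, 44.8% and 53.7% in the genotype contrasts on control diet and high sugar, and 17.9% in the interaction. Between 2 and 6 unchanged genes were called per contrast. The simulated reads were scaled jointly in every contrast, whereas the real genotype contrasts and interaction used the deposited values. The real genotype contrasts also gave more calls, 802 and 1255, than the 200 genes changed here. These shares therefore need not hold for the real contrasts. Alternatives covered the pseudocount (0.1 and 5), a minimum mean of 5, no filter, other scalings, the model, the groups in the model, a block for the replicate number and leaving out each library. For gene lists, ranges of adjusted p over the alternatives are those of camera with the preset correlation. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the rest.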

Results

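The series profiled fat body RNA of Drosophila larvae in a design of 2 diets by 2 genotypes, with 3 libraries in each of the 4 groups. It asks how a high-sugar diet changes fat body gene expression and how RNAi against svp in the fat body alters it. The libraries held 4380768 to 6556065 recovered reads over the 9367 genes tested. In a principal component analysis of 7405 genes, the first component took 38.9% of the variance and separated the genotypes, and the second took 21.7% and separated the diets. Mitochondrial transcripts, the ribosomal RNA mt:srRNA among them, took 0.41% to 5.71% of the reads of a library. Their share was 1.31% ± 0.90 (SD, n = 3) in the high-sugar libraries labelled svp RNAi and 3.33% ± 1.48 (SD, n = 3) in the high-sugar controls. The 6 genes annotated as nuclear ribosomal RNA or its pseudogenes took 0.53% to 4.62% of the reads of a library. This share was 2.56% ± 1.82 and 1.62% ± 0.24 on the control diet, in control and in the libraries labelled svp RNAi, and 0.92% ± 0.43 and 0.81% ± 0.21 on high sugar (SD, n = 3). The highest share, 4.62%, was that of control-diet control replicate 3, which also had the fewest reads.

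The target of the RNAi, svp (FBgn0003651), was higher and not lower in the libraries labelled svp RNAi. On the control diet its normalized abundance was 1558 ± 179 (SD, n = 3) in these libraries against 456 ± 73.8 (SD, n = 3) in control, a log2 fold change of 1.78 ± 0.16 (SE, limma, adjusted p = 6.8e-06). On high sugar it was 1790 ± 356 (SD, n = 3) against 641 ± 19.8 (SD, n = 3), a log2 fold change of 1.46 ± 0.16 (SE, limma, adjusted p = 2.2e-05). Every library labelled svp RNAi lay above every control library of its diet. The gene-level value of svp therefore does not show the fall that the label would give. It cannot tell reads of the hairpin counted as svp from a rise of the endogenous transcript. Every direction given here for genotype is that of the libraries labelled svp RNAi relative to control. The interaction of svp was -0.32 ± 0.22 (SE, limma, adjusted p = 0.59). Dcr-2, which the driver stock overexpresses, was abundant in all 4 groups, with group means from 34550 to 48560. The insulin receptor gene InR was at 285 ± 30.5 and 273 ± 18.8 (SD, n = 3) on the control diet and at 279 ± 36.8 and 293 ± 7.20 (SD, n = 3) on high sugar, in control and in the libraries labelled svp RNAi. The landing-site neighbour tio and the body-colour gene y gave no call in any contrast.

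**Figure D1:**
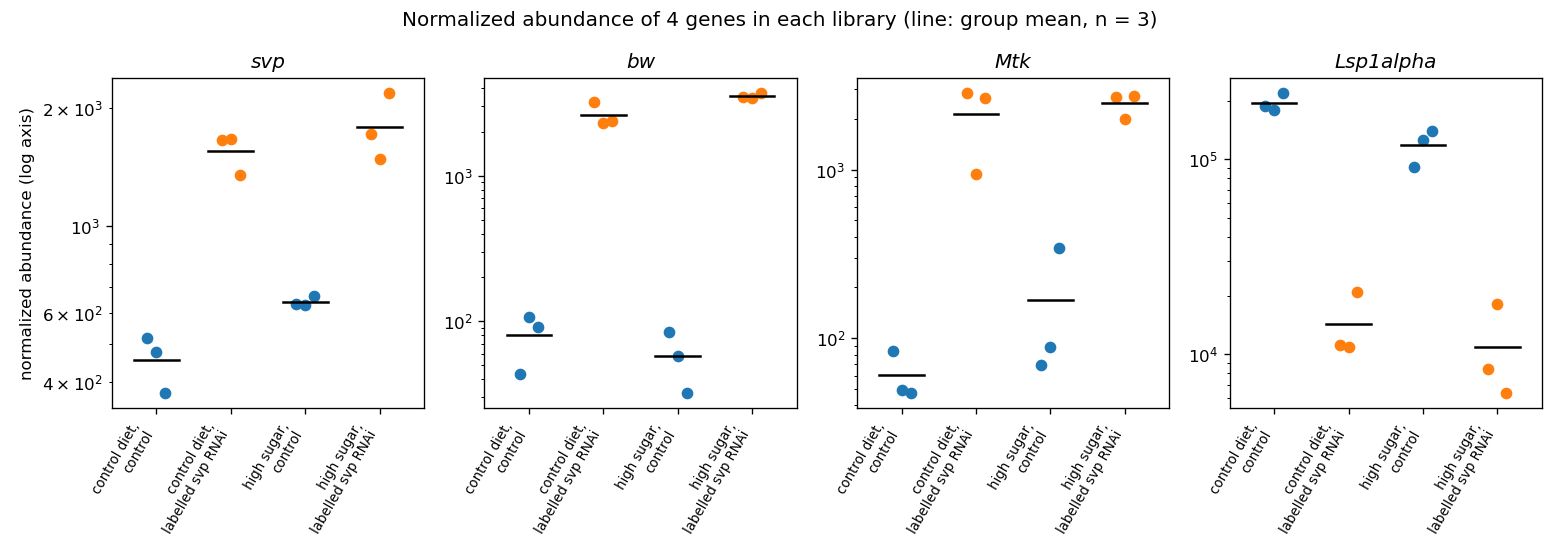
Normalized abundance (log axis) of svp, bw, Mtk and Lsp1alpha in each of the 12 libraries, by diet and genotype, with points for libraries and lines for group means (n = 3). In the libraries labelled svp RNAi, svp, bw and Mtk lie above all controls of their diet and Lsp1alpha lies below them.

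On the control diet, the largest rise in the libraries labelled svp RNAi was that of bw, a transporter of eye pigment precursors, from 80.8 ± 33.3 to 2624 ± 500 (SD, n = 3), a 33.9-fold change with an adjusted p of 5.3e-07 by limma. The antimicrobial peptide genes Mtk, Dro and AttA rose 32.6-fold, 22.6-fold and 21.1-fold, with adjusted p of 1.9e-05, 0.00014 and 9.7e-05 in limma, and CG30181, whose current symbol is ppk3, rose 23.9-fold. The replicates of these peptide genes were spread widely, as for AttA at 2360 ± 1450 (SD, n = 3). The largest falls were those of CG6385, CG4741, CG14528 and CG34291, which were 24.7-fold, 20.6-fold, 20.2-fold and 19.3-fold lower, and of CG32667, which fell by 3.91 on the log2 scale. CG6385, now named Sardh after sarcosine dehydrogenase, went from 1171 ± 202 to 51.5 ± 30.4 (SD, n = 3).

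Of the 14 antimicrobial peptide and peptidoglycan recognition genes measured, 6 rose and 2 fell (7 and 2 adjusted over the list alone), with a camera adjusted p of 0.00587 that became an adjusted p of 0.599 with an estimated correlation. Among those that fell was PGRP-SD, which encodes a recognition protein for bacterial cell walls and is named here after its value was seen: it fell by 3.22 on the log2 scale, from 253 ± 16.2 to 26.5 ± 5.17 (SD, n = 3, limma adjusted p = 9.3e-05). Of 5 Turandot and JAK/STAT genes, 3 rose (3 adjusted over the list alone, with 1 lower), with a camera adjusted p of 0.0146 and an adjusted p of 0.315 with an estimated correlation. The stress-induced secreted factor TotA, also named after its value was seen, was at 73510 ± 9150 against 6284 ± 374 (SD, n = 3, limma adjusted p = 1.1e-06). Over its alternatives the camera adjusted p of the Turandot list ranged from 0.00167 to 0.0535, the latter without control-diet control replicate 3.

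Muscle markers moved with genotype on the control diet: 12 of 13 fell (13 adjusted over the list alone), with a median log2 fold change of -1.22, a camera adjusted p of 2.67e-14 and an adjusted p of 0.315 with an estimated correlation. The troponin T gene up fell 2.86-fold, the myosin heavy chain gene Mhc 2.68-fold, the paramyosin gene Prm 2.33-fold and the tropomyosin gene Tm2 2.30-fold. Markers of other tissues also had medians below 0, at -0.654 for 10 neuron markers, -0.507 for 36 midgut markers, -0.471 for 9 salivary gland markers and -0.74 for 23 cuticle markers, with camera adjusted p of 0.0114, 0.0191, 0.00587 and 0.0173 and adjusted p of 0.599, 0.723, 0.599 and 0.599 with an estimated correlation. Over all genes, 1 neuron marker was called higher and 0 lower, 2 midgut markers higher and 2 lower, 0 salivary gland markers higher and 3 lower, and 0 cuticle markers higher and 2 lower. Adjusted over the list alone these were 1 and 7, 2 and 3, 0 and 3, and 0 and 6. Each of these 4 calls ended without at least 1 library. The midgut call, with camera adjusted p from 0.000736 to 0.659, ended without control-diet control replicate 3 and without replicate 1 or 3 labelled svp RNAi. The cuticle call (0.00147 to 0.0814) ended without that control and without replicate 2 or 3 labelled svp RNAi. The salivary gland call (2.57e-06 to 0.0731) ended without control replicate 2. The neuron call (0.00256 to 0.0738) ended without replicate 1 labelled svp RNAi. Medians of 9 imaginal disc markers and 5 Malpighian tubule markers were 0.045 and -0.072.

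On the control diet the called members of 5 metabolic lists were lower, alongside the lower muscle markers, and those of glycolysis went both ways. Of 13 genes of gluconeogenesis, glycogen and trehalose, 5 fell (7 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00142, and adjusted p = 0.599 with an estimated correlation). The trehalose transporter gene Tret1-1 fell by 1.44 ± 0.15 (SE) on the log2 scale. The gluconeogenic bisphosphatase gene fbp fell from 623 ± 108 to 285 ± 17.8 (SD, n = 3), the glycogen phosphorylase gene GlyP 1.97-fold and the UDP-glucose pyrophosphorylase gene UGP 1.60-fold. Of 19 genes of oxidative phosphorylation, 3 fell (4 adjusted over the list alone; camera adjusted p = 0.000822, and adjusted p = 0.599 with an estimated correlation). They were blw, Oscp and CoVa, at 1.38-fold, 1.42-fold and 1.44-fold, and their calls ended in 5, 5 and 8 of the 12 runs that left out 1 library, control-diet control replicates 2 and 3 and replicates 1 and 2 labelled svp RNAi among them for each. In 17 genes of lipogenesis and fat storage 4 fell, in 19 of fatty acid oxidation 3 fell, and in 13 of the TCA cycle 3 fell, with camera adjusted p of 0.00467, 0.00587 and 0.012 and an adjusted p of 0.599 for each with an estimated correlation. Adjusted over the list alone these counts were 6, 6 and 4. Without control-diet replicate 3 labelled svp RNAi all 3 list calls ended, and that of the TCA cycle also without control replicate 3. Over the alternatives their adjusted p ranged from 0.000335 to 0.0533, from 0.000162 to 0.0757 and from 0.00154 to 0.0677.

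Of 11 glycolysis genes, 1 rose and 2 fell on the control diet (1 and 6 adjusted over the list alone), with a median of -0.448, a camera adjusted p of 0.00923 and an adjusted p of 0.599 with an estimated correlation. The list call ended without control-diet control replicate 3, the library with the highest ribosomal RNA share, and its adjusted p ranged from 0.000192 to 0.0958 over the alternatives. The called genes, named after their values were seen, were the hexokinase genes Hex-C, 2.93-fold higher, and Hex-A, 1.58-fold lower, and the pyruvate kinase gene PyK, 1.48-fold lower. The call of Hex-C ended without control replicate 2 or replicate 1 labelled svp RNAi, and that of PyK in 5 of the 12 runs that left out 1 library, that of control replicate 3 among them. Of 9 basement membrane genes 3 fell (3 adjusted over the list alone; camera adjusted p = 0.00923, and adjusted p = 0.315 with an estimated correlation), and of 12 genes of oxidative defence 2 rose (5 adjusted over the list alone; camera adjusted p = 0.012, and adjusted p = 0.599 with an estimated correlation). They were Cg25C, trol and the collagen IV gene vkg, 2.54-fold, 2.28-fold and 2.32-fold lower, and the glutathione synthesis genes Gclc and Gclm, 3.19-fold and 1.83-fold higher, all named after their values were seen.

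Of the 28 proteasome genes, 8 rose on the control diet (13 adjusted over the list alone), 27 had a log2 fold change above 0, and the median was 0.294 (camera adjusted p = 1.25e-07, and adjusted p = 0.599 with an estimated correlation). Rpn3, a subunit of the regulatory particle, rose from 593 ± 44.5 to 848 ± 91.6 (SD, n = 3, limma adjusted p = 0.011), and Pros26 rose 1.49-fold, although both calls ended without control-diet control replicate 2 or replicate 1 labelled svp RNAi, and that of Pros26 also without replicate 2 labelled svp RNAi. Of the 6 larval storage protein genes 3 fell (4 adjusted over the list alone), with a camera adjusted p of 0.00205, and an adjusted p of 0.346 with an estimated correlation. Over the alternatives its camera adjusted p ranged from 0.000335 to 0.346, the latter under quantile normalization. Lsp1alpha, a major serum protein of the larva named here after its value was seen, fell from 195500 ± 19900 to 14360 ± 5750 (SD, n = 3, limma adjusted p = 1.1e-05). The list did not move as a whole. Its member Lsp2 took 10.5% to 12.7% of the reads of the libraries labelled svp RNAi and 7.3% to 9.9% in control. In all, 802 genes passed the threshold on the control diet, 400 higher and 402 lower, of 9367 tested with limma, and 369 of them changed at least 2-fold. The 3 against 3 libraries did not overlap in 26.1% of genes, where chance gives 10%.

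On high sugar, bw again had the largest rise, from 57.8 ± 26.0 to 3523 ± 132 (SD, n = 3), 64.3-fold higher in the libraries labelled svp RNAi with a limma adjusted p of 4.9e-08. CG30181, CG33462 and Dro rose 25.1-fold, 24.5-fold and 19.6-fold, and the odorant-binding protein gene Obp49a rose by 4.32 ± 0.44 (SE) on the log2 scale. CG15067, now named BomBc2 after the bomanin immune peptides, CG34291, CG4991, CG32667 and the poly(A) polymerase gene wisp fell 24.5-fold, 21.9-fold, 20.1-fold, 18.5-fold and 18.8-fold. Lsp1alpha and Lsp1beta, both named after their values were seen, fell from 118900 ± 24500 to 10980 ± 6320 and from 308500 ± 62900 to 75130 ± 6820 (SD, n = 3), with limma adjusted p of 1.4e-05 and 0.0013. Of the 6 storage protein genes, 4 fell (4 adjusted over the list alone; camera adjusted p = 0.00287, and adjusted p = 0.543 with an estimated correlation). Here too Lsp2 went another way, with 13.7% to 16.0% of the reads of the libraries labelled svp RNAi and 9.2% in each control.

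Muscle markers were lower here too, with 7 of 13 fallen (10 adjusted over the list alone), a median log2 fold change of -0.813, a camera adjusted p of 2.23e-06 and an adjusted p of 0.616 with an estimated correlation. The projectin gene bt fell 2.47-fold, TpnC47D 2.37-fold, Mhc 2.05-fold and Tm2 1.91-fold. Of 10 neuron markers, 6 fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.00143, and adjusted p = 0.543 with an estimated correlation). The pan-neuronal genes elav and futsch and the glutamate transporter gene VGlut fell 2.01-fold, 1.89-fold and 2.45-fold, whereas the synaptotagmin gene Syt1 rose 2.38-fold, from 1683 ± 29.3 to 4038 ± 597 (SD, n = 3, limma adjusted p = 4.9e-05). The median of 36 midgut markers was -0.806, with 3 called higher and 2 lower (3 and 11 adjusted over the list alone), a camera adjusted p of 0.0017 and an adjusted p of 0.621 with an estimated correlation. The camera call ended without high-sugar control replicate 1, and its adjusted p ranged from 6.97e-05 to 0.0926 over the alternatives.

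Of 19 genes of oxidative phosphorylation, 3 fell on high sugar too (3 adjusted over the list alone; median -0.344, camera adjusted p = 0.00287, and adjusted p = 0.621 with an estimated correlation). Of 19 genes of fatty acid oxidation 3 fell as well (8 lower and 2 higher adjusted over the list alone; median -0.238, camera adjusted p = 0.0099, and adjusted p = 0.621 with an estimated correlation). Both camera calls held in all 22 alternatives run with the preset correlation. The called genes, named after their values were seen, were the ATP synthase genes ATPsyn-beta, Oscp and sun, 1.34-fold, 1.51-fold and 1.65-fold lower, and the fatty acid oxidation genes Acox57D-p, scu and wal, 1.82-fold, 1.92-fold and 1.61-fold lower. The calls of ATPsyn-beta, Oscp and sun ended in 8, 3 and 4 of the 12 runs that left out 1 library. For each of them, high-sugar control replicate 3 and high-sugar labelled svp RNAi replicates 1 and 3 were among those libraries. These falls stood beside lower muscle markers. The mitochondrial share was 1.31% ± 0.90 in the libraries labelled svp RNAi and 3.33% ± 1.48 (SD, n = 3) in control. As mt:srRNA is counted in it, the share does not measure mitochondrial messenger RNA alone.

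Genes of DNA replication and the cell cycle rose on high sugar in the libraries labelled svp RNAi: 8 of 18 were higher (11 higher and 1 lower adjusted over the list alone), with a median of 0.607, a camera adjusted p of 0.0012 and an adjusted p of 0.543 with an estimated correlation. The ribonucleotide reductase gene RnrS rose from 118 ± 16.3 to 261 ± 16.1 (SD, n = 3, limma adjusted p = 0.00018), and the replicative helicase genes Mcm2, Mcm7 and Mcm6 rose 1.85-fold, 1.94-fold and 1.77-fold. Of 84 cytosolic ribosomal protein genes 16 rose and 1 fell (17 and 1 adjusted over the list alone), with a camera adjusted p of 2.23e-06 and an adjusted p of 0.621 with an estimated correlation. RpL26, RpL40 and RpL35A rose 1.51-fold, 1.49-fold and 1.41-fold and RpL38 fell 1.99-fold, and each of the 4 calls ended without high-sugar control replicate 3 and again without high-sugar labelled svp RNAi replicate 3. Those of RpL26, RpL40 and RpL35A also ended without control replicate 2, and that of RpL40 without replicate 1 labelled svp RNAi. Of 28 proteasome genes 2 fell (0 adjusted over the list alone), with a median of -0.178, a camera adjusted p of 0.0205 and an adjusted p of 0.661 with an estimated correlation. That list call ended without high-sugar control replicate 2 and without high-sugar labelled svp RNAi replicate 1, and its adjusted p ranged from 0.000638 to 0.11 over the alternatives.

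The antimicrobial list had 5 genes higher and 2 lower on high sugar (7 and 2 adjusted over the list alone), with a camera adjusted p of 0.0099 and an adjusted p of 0.621 with an estimated correlation. In all, 1255 genes passed the threshold with limma, 672 higher and 583 lower, and 550 of them changed at least 2-fold. The count was 785 without high-sugar labelled svp RNAi replicate 3, which had the lowest mitochondrial share at 0.41%, and 806 without high-sugar control replicate 3. The libraries did not overlap in 31.7% of genes, where chance gives 10%.

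The genotype contrasts on the 2 diets, which share no library, had a Pearson correlation of 0.619 and a Spearman correlation of 0.443 across 9367 genes, which are not independent replicates. Of the calls, 253 genes were higher on both diets and 244 were lower on both, where independent lists would share 28.7 and 25. In 3 genes the calls had opposite signs, 2 of them higher on the control diet and 1 higher on high sugar.

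**Figure D2:**
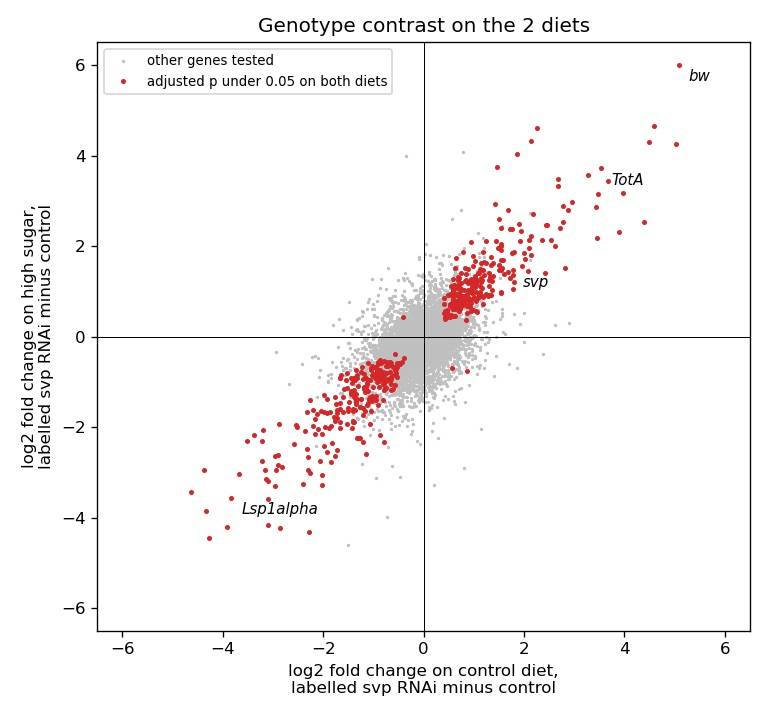
Log2 fold change of each of the 9367 genes between the libraries labelled svp RNAi and control, on the control diet (horizontal axis) and on high sugar (vertical axis). Red points passed an adjusted p of 0.05 on both diets, and 253 of them are higher and 244 lower on both.

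In control larvae, the ribosomal RNA share was 2.56% ± 1.82 on the control diet and 0.92% ± 0.43 (SD, n = 3) on high sugar. On high sugar, 4 of 17 genes of lipogenesis and fat storage rose (9 higher and 1 lower adjusted over the list alone), with a camera adjusted p of 3.85e-05 and an adjusted p of 0.353 with an estimated correlation. The desaturase gene desat1 rose from 1761 ± 207 to 3552 ± 880 (SD, n = 3), a log2 fold change of 0.99 ± 0.17 (SE, limma, adjusted p = 0.0072). The perilipin gene Lsd-1 rose 1.70-fold, the malic enzyme gene Men 1.94-fold, and the acetyl-CoA synthetase gene AcCoAS from 2627 ± 304 to 5387 ± 1540 (SD, n = 3). These 3 calls ended in 2, 8 and 4 of the 12 runs that left out 1 library, high-sugar control replicate 3 among them for each. Of 19 genes of fatty acid oxidation 2 rose (8 adjusted over the list alone; camera adjusted p = 0.000114, and adjusted p = 0.572 with an estimated correlation). They were the acyl-CoA oxidase genes Acox57D-d, 2.27-fold higher, and CG9527, 1.68-fold higher. Of 9 genes of sugar sensing, AcCoAS alone was called over all genes (5 rose adjusted over the list alone; camera adjusted p = 0.000517, and adjusted p = 0.353 with an estimated correlation), and the transcription factor gene cbt was at 258 ± 7.84 on high sugar against 177 ± 37.9 on control diet (SD, n = 3, limma adjusted p = 0.19). ACC, ATPCL, AcCoAS and CG3523 are in both the sugar-sensing and the lipogenesis list, so these list calls are not separate results. Mondo and sug were left out of the sugar-sensing list because their names differ only in case from others or repeat.

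Of 7 hemocyte markers, 2 fell in control larvae on high sugar (3 adjusted over the list alone), with a camera adjusted p of 0.000517 and an adjusted p of 0.161 with an estimated correlation. The clotting factor gene Hml fell from 861 ± 149 to 451 ± 14.6 (SD, n = 3, limma adjusted p = 0.0017) and the scavenger receptor gene Sr-CI fell 2.49-fold. Of 9 basement membrane genes 2 fell (4 adjusted over the list alone; camera adjusted p = 0.000113, and adjusted p = 0.0746 with an estimated correlation). They were the collagen IV gene Cg25C, 1.54-fold lower, and the perlecan gene trol, 1.62-fold lower, and their calls ended in 6 and 7 of the 12 runs that left out 1 library and on the deposited values. Muscle markers moved the same way, with a median of -0.467, 1 of 13 called (6 lower and 1 higher adjusted over the list alone), a camera adjusted p of 0.000614 and an adjusted p of 0.623 with an estimated correlation. The called gene was up, 1.75-fold lower, whose call ended without replicate 2 or 3 of either diet's controls. All 28 proteasome genes had a log2 fold change above 0, with a median of 0.342, but only Pros26 passed over all genes, and not in 8 of the 12 runs that left out 1 library (19 adjusted over the list alone; camera adjusted p = 1.59e-12, and adjusted p = 0.353 with an estimated correlation). Rpn11 was at 645 ± 37.0 against 461 ± 58.8 (SD, n = 3, limma adjusted p = 0.055).

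The genes with the largest rise on high sugar in control larvae were the cytochrome P450 gene Cyp4e3, from 11 ± 1.86 to 1188 ± 734 (SD, n = 3, limma adjusted p = 1.8e-05), followed by CG14205, CG11898, CG15534 and CG13947 at 35.1-fold, 14.2-fold, 13.2-fold and 13.1-fold. The largest falls were in CG6283, CG9672, CG6295, CG3819 and the amylase gene Amy-d, at 15.7-fold, 10.9-fold, 10.6-fold, 8.92-fold and 7.66-fold. Their control-diet libraries were widely spread, as for CG6283 at 304 ± 300 (SD, n = 3), and limma voom did not call CG11898, CG6283, CG9672 or CG6295. The call of CG9672 also ended without control-diet control replicate 3 and without high-sugar control replicate 1 or 3. Amy-d is also one of the midgut markers, a list that did not pass by camera in this contrast. Whether gut tissue carried over with the fat body had a part in these falls was not tested. In all, 178 genes passed the threshold with limma, 118 higher and 60 lower, and 1449 had an unadjusted p under 0.05. On the deposited values, whose diets were adjusted separately and whose median gene was 0.113 higher on high sugar, 260 genes were higher and 47 lower. The count was 103 without high-sugar control replicate 3, 108 without control-diet control replicate 2 and 117 without control-diet control replicate 3.

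In the libraries labelled svp RNAi, 792 genes passed the threshold between diets, 443 higher and 349 lower on high sugar. Of the 17 lipogenesis genes 8 rose (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.37e-05, and adjusted p = 0.416 with an estimated correlation), and of the 9 sugar-sensing genes 5 rose (8 adjusted over the list alone; camera adjusted p = 0.000199, and adjusted p = 0.288 with an estimated correlation). As these lists share ACC, ATPCL, AcCoAS and CG3523, their calls are not separate results. Of 18 genes of DNA replication and the cell cycle 5 rose, and of 18 glutathione S-transferase genes 4 fell (10 higher and 1 lower, and 9 lower, adjusted over the list alone), with camera adjusted p of 0.00139 and 0.000137 and an adjusted p of 0.416 for both with an estimated correlation. The largest rises were in CG14265, Cyp4e3, CG14205, CG3348 and CG13947, at 21.8-fold, 18.3-fold, 12.9-fold, 11.5-fold and 10.3-fold. The largest falls were in CG9672, CR40582, CG8665, CG3819 and the mitochondrial ribosomal RNA mt:srRNA, at 9.75-fold, 9.12-fold, 7.13-fold, 6.92-fold and 6.6-fold, beside a mitochondrial share of 1.31% ± 0.90 on high sugar and 3.64% ± 1.81 (SD, n = 3) on the control diet. The calls of CG9672 and CG13947 were not made by limma voom. That of CG9672 also ended without control-diet or high-sugar replicate 3 of these libraries, and that of mt:srRNA without control-diet replicate 2 or 3. Of 7 hemocyte markers 3 fell (4 adjusted over the list alone; median -0.627, camera adjusted p = 0.00198, and adjusted p = 0.288 with an estimated correlation). Of 10 neuron markers 2 fell (4 adjusted over the list alone; median -0.522, camera adjusted p = 0.0192, and adjusted p = 0.563 with an estimated correlation). That list call ended without control-diet replicate 3, with adjusted p from 0.0046 to 0.208 over the alternatives. The muscle markers had a median of 0.006 with 0 of 13 called by limma (camera adjusted p = 0.897).

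By camera, 8 further lists passed in this contrast. Of 9 basement membrane genes 3 fell (4 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0152, and adjusted p = 0.288 with an estimated correlation). Of 19 genes of fatty acid oxidation 3 rose and of 10 genes that respond to FOXO or fasting 4 rose (3 and 5 adjusted over the list alone), with camera adjusted p of 0.00625 and 0.0172 and adjusted p of 0.68 and 0.474 with an estimated correlation. Of 84 cytosolic ribosomal protein genes 4 rose (1 adjusted over the list alone; camera adjusted p = 0.000817, and adjusted p = 0.82 with an estimated correlation). Counts were 2 of 13 higher for gluconeogenesis, glycogen and trehalose, 2 of 21 for insulin and TOR signalling, 2 of 5 for iron handling and 0 of 28 for the proteasome by limma. Adjusted over the list alone they were 3, 3, 2 and 0, with camera adjusted p of 0.0196, 0.0191, 0.0196 and 0.0192 and adjusted p of 0.68, 0.68, 0.329 and 0.82 with an estimated correlation. The proteasome median was -0.157. Of these 8 calls, that of the basement membrane list alone held in all alternatives run with the preset correlation. Quantile normalization ended those of the ribosomal proteins (2.4e-05 to 0.263 over the alternatives), fatty acid oxidation (0.000408 to 0.0754), gluconeogenesis (0.00583 to 0.313), insulin and TOR signalling (0.00343 to 0.241) and iron handling (0.00746 to 0.0754). Those of gluconeogenesis, insulin and TOR signalling and the FOXO list (0.00343 to 0.141) ended without control-diet replicate 3 of these libraries, and that of gluconeogenesis also without high-sugar replicate 1. Those of the ribosomal proteins and iron handling ended without control-diet replicate 2. That of the proteasome (5.15e-05 to 0.214) ended on the deposited values and without control-diet replicate 1 or 2 or high-sugar replicate 1.

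The count of 792 in the diet contrast of the libraries labelled svp RNAi was 273 without high-sugar replicate 3, 478 without high-sugar replicate 1, 518 without high-sugar replicate 2, 457 without control-diet replicate 2 and 376 without control-diet replicate 3 of these libraries. On the deposited values, 1004 genes were higher and 279 lower, with a median gene 0.092 higher. Across 9367 genes, the diet contrasts of the 2 genotypes had a Pearson correlation of 0.468 and a Spearman correlation of 0.35. They shared 75 higher and 24 lower calls, where independent lists would share 5.6 and 2.2, and 170 of the 178 genes called in control had the same sign in the libraries labelled svp RNAi.

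The diet response itself differed between genotypes in 18 genes by limma, 10 with a positive and 8 with a negative interaction, while 1105 genes had an unadjusted p under 0.05 and limma voom on the recovered reads called 25. The largest positive values were in CG6839 (4.35 ± 0.59, SE), the P450 genes Cyp304a1 and Cyp6g2, CG3074 and the maltase gene Mal-A6. The largest negative values were in the double-stranded RNA binding protein gene blanks (-3.71 ± 0.58, SE), CG8665, CG15553, CG1208 and CG8389. CG8665 had 429 ± 90.8 and 558 ± 63.2 jointly scaled reads in control on the control diet and on high sugar, and 254 ± 44.0 and 37.3 ± 16.9 in the libraries labelled svp RNAi (SD, n = 3). CG15553 had 34.6 ± 10.3 and 248 ± 48.5 in control, and 183 ± 41.4 and 192 ± 48.4 in the libraries labelled svp RNAi (SD, n = 3). Leaving out single libraries moved the count of 18 between 6 and 30. It was 6 without high-sugar control replicate 2 or 3, 28 without its replicate 1, and 6 and 9 without high-sugar labelled svp RNAi replicates 3 and 1. Without control-diet control replicate 2 it was 7, and without control-diet labelled svp RNAi replicates 1, 2 and 3 it was 10, 8 and 30. The calls of CG6839, CG8665, CG15553 and CG8389 held in all of these runs, whereas that of blanks ended in 5.

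Among the lists, all 28 proteasome genes had a negative interaction, with a median of -0.509, 0 calls over all genes (18 adjusted over the list alone), a camera adjusted p of 2.18e-15 and an adjusted p of 0.831 with an estimated correlation. Of 18 glutathione S-transferase genes, 17 had a negative interaction (7 called adjusted over the list alone; median -0.744, camera adjusted p = 2.73e-06, and adjusted p = 0.831 with an estimated correlation). The interaction uses all 12 libraries, so these results are not separate from the other contrasts. The proteasome rises with diet in control and with genotype on control diet share the control-diet control libraries. For glutathione S-transferase and DNA replication genes, the diet contrast in the libraries labelled svp RNAi and the genotype contrast on high sugar share the high-sugar labelled libraries. The muscle markers had a median interaction of 0.449 (0 calls over all genes and 0 adjusted over the list alone by limma; camera adjusted p = 0.0038, and adjusted p = 0.975 with an estimated correlation). That call ended without control-diet labelled svp RNAi replicate 3 or high-sugar control replicate 2, with adjusted p from 0.000106 to 0.16 over the alternatives.

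**Figure D3:**
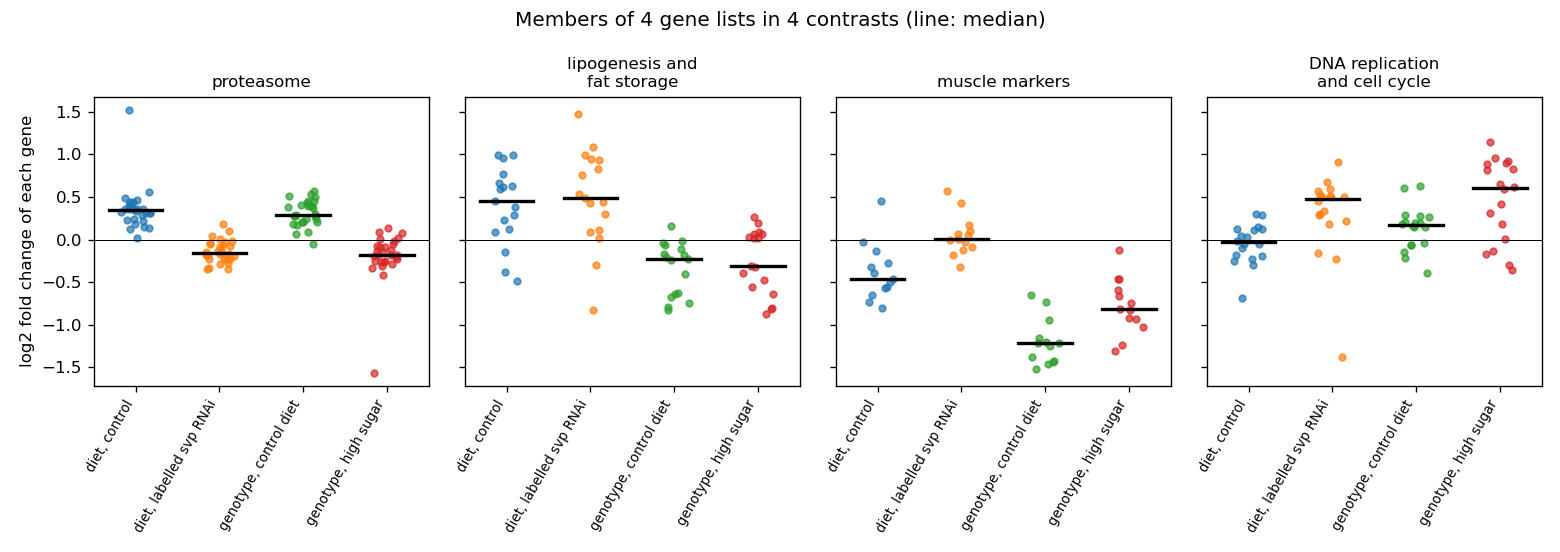
Log2 fold change of each member of 4 gene lists in the diet contrasts of the 2 genotypes and the genotype contrasts on the 2 diets, with lines for medians. The median of the 28 proteasome genes is 0.342 and 0.294 in the diet contrast of control and the genotype contrast on control diet, and -0.157 and -0.178 in the other 2. The former contrasts share the control-diet control libraries, and the latter share the high-sugar libraries labelled svp RNAi.

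Diet in control and genotype on high sugar share the high-sugar control libraries. Across 9367 genes their fold changes had a Pearson correlation of -0.15 and a covariance of -0.0433, while 100 simulations without any effect gave means of -0.499 and -0.0474, so the covariance differed by 0.0041. The covariance is thus no more negative than the shared libraries alone gave on average. Among calls, 24 genes were higher in the first and lower in the second and 17 the reverse, where independent lists would share 7.4 and 4.3, and 17 were higher and 8 lower in both, against 8.4 and 3.7. The shared libraries enter these contrasts with opposite sign, which raises opposite calls, so the numbers for independent lists are no measure of chance for them. With 3 shared controls no split leaves at least 2 libraries on each side, so part or all of the excess of opposite calls can come from the shared libraries.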

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

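The tests on the level of svp and the count of regrouped libraries were chosen only after the results were seen. The interaction was planned.

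Genes were looked at again where the diet contrast differed between genotypes by a test of the difference. This held for 18 genes. The interaction on the log2 scale was -3.71 for blanks, -3.26 for CG8665, -2.76 for CG15553, -2.64 for CG1208 and -2.09 for CG8389, and 4.35 for CG6839, 2.18 for Cyp304a1, 1.99 for Cyp6g2, 1.68 for CG3074 and 1.62 for Mal-A6. Without 1 library, the call of Cyp304a1 ended in 10 of 12 runs, that of Cyp6g2 in 7, those of blanks, CG1208 and CG3074 in 5 each and that of Mal-A6 in 4. Of 100 regroupings of genotype within diets, the real one included, 8 gave as many calls as the real 18. They do not decide on chance for this count, since regrouping carries the genotype effects into the interaction. The highest other regrouping gave 1787: it exchanges the genotypes on 1 diet and so adds the 2 genotype effects. Of the rest, which mix genotypes, 6 gave as many calls and the highest gave 378.

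Of the gene lists, 6 differed in diet response between genotypes by camera with a preset correlation. The median interactions were -0.509 for the proteasome, -0.744 for glutathione S-transferases, 0.26 for cytosolic ribosomal proteins, 0.441 for DNA replication and cell cycle, 0.449 for muscle markers and -0.212 for mitochondrial ribosomal proteins. With an estimated correlation the smallest adjusted p was 0.831 and the largest 0.975. Quantile normalization ended the camera call of the cytosolic ribosomal proteins, whose adjusted p ranged from 2e-10 to 0.177 over the alternatives. That of the mitochondrial ribosomal proteins ended there and in 5 runs without 1 library, with adjusted p from 0.000147 to 0.59, and that of the muscle markers in 2 such runs.

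A signal also stood in rows left out of the tests because names differ only in case. The eye-colour gene w, a marker that many transgenes carry, was 2.66 higher on the log2 scale in the high-sugar libraries labelled svp RNAi than in control, at 4203 ± 831 against 658 ± 86.7 (SD, n = 3), and higher in 3 of 3 libraries. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 can give. In the 38 such names with more than 1 spelling, each spelling had its own high-sugar values. The gene spelled W was at 47.2 ± 5.09 against 57.2 ± 4.07 (SD, n = 3) there, so the high-sugar values are taken as those of the spelling they stand under. On the control diet w and W shared 2 sets, and which is w is not known: 1 was at 3375 ± 385 against 458 ± 68.2 and the other at 46.3 ± 3.45 against 47.6 ± 10.5 (SD, n = 3).

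The pattern weighed here is that svp was higher in the libraries labelled svp RNAi. Swapped genotype labels would lower w in those libraries if the RNAi stock carries the marker and the control stock carries less of it. The 2.66 higher value argues against a swap only under these premises, the former from general knowledge of such stocks. A further premise is that the high-sugar values under the spelling w are those of w. What the control stock carries was not examined, and w was at 658 ± 86.7 (SD, n = 3) in the high-sugar controls. Reads from the hairpin transcript counted as svp could raise svp on both diets alike, and the interaction of -0.32 ± 0.22 (SE) does not separate this from a rise of the endogenous transcript, since each gene has 1 value and reads over the hairpin's exon are not seen apart. A rise of the endogenous transcript is open for the same reason: the lowest library labelled svp RNAi was 2.23 times the highest control library of its diet. Whether svp protein was lower was not measured here.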

How the results depend on the processing

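The scaling by recovered reads and limma voom were chosen after seeing the data, and the other alternatives before. Of 120 named calls under 2718 alternatives, 2507 kept direction and side of the threshold, 211 fell short of it and 0 changed sign, and 82 calls held under every alternative run. svp stayed called, from 1.64 to 1.88 on the control diet and from 1.31 to 1.59 on high sugar without single libraries.

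Without an intensity trend, calls numbered 101 for diet in control, 479 for diet in the libraries labelled svp RNAi and 10 for the interaction. Requiring a log2 fold change of at least 1, which by construction removes calls, left 112, 293, 369 for genotype on control diet and 550 for genotype on high sugar. On the deposited values, diet calls numbered 307 in control and 1283 in the libraries labelled svp RNAi; the separate adjustment of the diets shifts the median gene there. A pseudocount of 5 gave 28 interaction calls, and the cause was not tested. Without single libraries, calls ranged from 103 to 236 and from 273 to 878 for diet in the 2 genotypes, from 562 to 872 and from 785 to 1355 for genotype on the 2 diets, and from 6 to 30 for the interaction. Fewer libraries were fitted there.

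With an estimated correlation 0 lists passed in each contrast, against 7, 14, 17, 11 and 6 with the preset one for diet in control, diet in the libraries labelled svp RNAi, genotype on control diet, genotype on high sugar and interaction. The unadjusted p with an estimated correlation was under 0.05 for 4, 5, 4, 3 and 2 lists. fry, which asks another question, called 7 on each diet for genotype and 0 for the interaction. Quantile normalization gave 9 lists for diet in the libraries labelled svp RNAi and 18 for genotype on high sugar; the cause was not tested. Without single libraries the counts of lists ranged from 7 to 12, 10 to 17, 12 to 18, 9 to 16 and 4 to 9.

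Correlations across genes moved with Spearman's rank version to 0.35 for diet between genotypes, 0.443 for genotype between diets and -0.104 for diet against genotype on high sugar. Genotype between diets was 0.595 with a pseudocount of 0.1 and 0.66 with one of 5. Without single libraries they ranged from 0.381 to 0.488, 0.556 to 0.631 and -0.252 to -0.111. The cause of these moves was not tested.

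Replicate numbers did not pair the samples: correlations of deviations between same-numbered libraries ran from -0.24 to 0.19, 2 of 18 were over 0.1, and a library correlated best with its own number in 13 of 36 comparisons, so not every one did. A replicate block gave 187, 761, 801, 1201 and 25 calls in the 5 contrasts in the order above. With it, Cg25C, Men, Pros26 and trol were not called for diet in control, nor was ATPsyn-beta for genotype on high sugar, and the other named calls were.

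The filter at a mean of 1 removed no gene, so a run without it tests nothing. The planned count models on recovered reads were not run. A median-ratio scaling was not a separate run for the diet contrasts, which use it, and a fit of 2 groups cannot give the interaction. Depth limits low genes most.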

Other observations

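The test of chromosome arms was written before its result was seen. The tests on muscle markers and the counts of regrouped libraries were chosen after the results they bear on were seen.

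Of 18 glutathione S-transferase genes, 4 rose and 1 fell on the control diet in the libraries labelled svp RNAi (7 and 1 adjusted over the list alone), with a median log2 fold change of 0.239 and a camera adjusted p of 0.0989. On high sugar 1 rose and 4 fell (2 and 6 adjusted over the list alone), with a median of -0.515, a camera adjusted p of 0.0324 and an adjusted p of 0.621 with an estimated correlation. That camera call ended in 3 runs without 1 library (high-sugar control replicate 1 or 3, or replicate 2 labelled svp RNAi), with adjusted p from 0.00765 to 0.105. The test of the difference between diets, the interaction, had a camera adjusted p of 2.73e-06 and an adjusted p of 0.831 with an estimated correlation. Cytochrome P450 genes changed in both directions, with 10 of 59 higher and 6 lower on the control diet and 12 higher and 11 lower on high sugar, and the list as a whole did not pass (camera adjusted p = 0.536 and 0.82). Of 17 genes of amino acid and one-carbon metabolism, 4 rose and 6 fell on the control diet and 3 rose and 4 fell on high sugar (camera adjusted p = 0.212 and 0.284). TotA, named after its value was seen, was at 130700 ± 50400 against 9631 ± 2320 on high sugar (SD, n = 3, limma adjusted p = 5.6e-07).

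The male dosage compensation RNA gene roX1 was read in all these female-labelled groups and fell by 1.02 on the log2 scale on high sugar in the libraries labelled svp RNAi, to 60.9 ± 24.2 against 119 ± 24 (SD, n = 3, limma adjusted p = 0.046). Its call ended in 8 of 12 runs without 1 library. It was chosen after its value was seen.

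Muscle markers were lower in the libraries labelled svp RNAi, and medians on the control diet and high sugar were also below 0 for markers of neurons (-0.654 and -0.963), midgut (-0.507 and -0.806), cuticle (-0.74 and -0.282) and salivary gland (-0.471 and -0.259). Imaginal disc markers had medians 1.26 ± 0.13 and 0.76 ± 0.18 (SE) above those of muscle on the control diet and high sugar. For Malpighian tubule markers the medians were 1.15 ± 0.12 and 0.69 ± 0.12 (SE) above, so neither list fell as muscle did. Whether disc or tubule tissue was carried over with the control fat bodies is not known, and tissue that was absent could not fall. These values therefore cannot decide on a like fall of every other tissue. A lower carry-over of several tissues, muscle among them, stays open and was not tested. Less muscle tissue on the dissected fat bodies is a candidate explanation: the 13 markers varied together between libraries of 1 group, with a mean correlation of 0.58 that lay at percentile 100 of 1000 random lists of like abundance, whose 95th percentile was 0.22. Muscle genes regulated together in remaining tissue would also vary together, so lower muscle expression in these larvae stays open and was not tested.

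Of the genes called on both diets in 1 direction, 497 in all, a candidate explanation was sequence variants linked to an insertion on the left arm of chromosome 2. The arm held 18.5% of the 491 of these genes with a known arm and 17.9% of all 9163 genes with one. The odds ratio was 1.05 (95% interval 0.82 to 1.33, Fisher's exact adjusted p = 0.95 over 5 arms). On the premise that the insertion lies on this arm, this argues against variants across the arm that change genes of the same arm as the source of most of these calls. Variants spread over several arms would not show in this test, nor would a variant on this arm that changes genes on other arms. Beyond tio, which gave no call, single genes near an insertion were not examined, and an effect of the genotype itself stays open, untested.

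With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. Each real split had the most calls, in 1 of 10 splits: 178 against at most 4 in another split for diet in control, 792 against 1 for diet in the libraries labelled svp RNAi, 802 against 0 for genotype on control diet and 1255 against 0 for genotype on high sugar. The other splits mix the groups, so a difference between the real groups widens the spread within them and lowers their calls. Their counts are therefore not those that chance alone would give.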
